A study of Homo sapiens with 4 samples.

How the data were processed

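RNA abundance was measured in A549 and H441, 2 established human lung adenocarcinoma cell lines, 48 h after transfection with a control siRNA (siNTC) or an siRNA named for TAZ (siTAZ), the transcriptional co-activator encoded by WWTR1. Each of the 4 combinations of line and siRNA was hybridised to 1 Affymetrix whole-transcript array, so no group has a replicate. Per the labels' protocols, the siRNAs were delivered with a lipid reagent, total RNA was column-purified, and biotin-labelled fragments of single-stranded cDNA were hybridised. The siRNA sequences, and whether siTAZ was a pool, are not given in the sources used here.

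The deposited values are log2 probe set signals made by the authors with RMA, per the submitters' processing notes. Its version, the software and whether the 4 arrays were normalized together are not given in the sources used here. The log2 scale was taken from the values, which ran from 4.20 to 14.83 over 28869 probe sets, with no scanner values to set them against. RMA compresses differences of dim probe sets, so their folds are understated. The number of arrays, 1 per group, limits the precision of every value.

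Probe sets were named through the platform's annotation table: 19310 had 1 gene symbol, 1752 had several and 7807 had none there. All but 31 of the single-symbol probe sets had an Entrez identifier in the GRCh38.p14 gene table, which was used for names only. No genome coordinates are given, since no source used here names the build of the probe sets. For the 685 genes with more than 1 probe set, the probe set with the highest mean over the 4 arrays was used, which left 18377 genes. Of the named genes with 2 probe sets, those of BIRC5 and CFLAR disagreed in sign in A549 and those of RPL34 in H441.

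Within a line, the siTAZ log2 value minus the siNTC value was computed for each gene, and a gene was counted where the higher of the 2 arrays was at or above the median of the whole table (6.13), which kept 11405 genes in A549 and 11911 in H441. These differences have no replicate check and no p-value. Over both lines, limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) was fitted to the 4 arrays with cell line as a block, on 12740 genes whose highest value reached that median, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. The fit has 1 residual degree of freedom, which measures how far the responses of the 2 lines differ, with a prior worth 22.3 degrees of freedom taken from all genes. A call therefore rests on 2 lines, with no repeat within either. The difference of response between the lines could not be tested, because 4 arrays leave no residual degree of freedom for it. The cell line coefficient of the same fit compared A549 with H441.

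Lists of genes were fixed before the data were examined, 21 in all, together with the tests, the alternatives and the rule for naming genes. For each list and line, the median log2 difference of the members at or above the table median was placed among 10000 random lists of the same size matched on mean expression in 20 bins. A list was said to stand apart under the 2.5th or over the 97.5th percentile, which chance gives in 5% of lists. These percentiles describe these arrays and are not p-values. Genes were named by this rule: WWTR1 and YAP1; per line the 10 genes per direction with the largest change among those at least 2-fold; over both lines the 10 per direction with the largest smaller-of-the-lines difference and the 10 with the smallest p; up to 4 members per list with the largest mean absolute difference; 8 per direction for A549 against H441; and CCN1, CCN2, ANKRD1, AXL, BIRC5 and TEAD1 whatever their values. AREG was on that list as well and is not analysed here, because no probe set used here has it as its single symbol. MYOF, FJX1, NUAK2, HSP90AA6P, SNORD44, SNORD49A, SNORD75 and SNORD79 fall outside the rule and were named after their values were seen. Up to 5 genes per orientation at least 1.5-fold changed in opposite directions were to be named, and no gene qualified.

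On simulated arrays of the same 12740 genes with noise set from the spread, across genes, of the difference between the 2 lines' responses, the limma fit recovered 88% of 200 genes changed by 0.6 on the log2 scale in both lines and 100% of those changed by 1, with 9 and 14 false calls, and made 0 calls with no change. Of 40 simulated lists with no shift, 2 stood apart, and all 40 did after a shift of 0.3. The simulated noise had the same SD for every gene and was independent between genes, and simulated changes were equal in both lines. Spreads of real genes differ and members of a real list may move together, so these rates need not hold for the real arrays. Of the 315 real calls, 128 reached 1.5-fold on average, and the smallest was 0.43 on the log2 scale. Recovery of changes under 0.6 was not simulated. The simulated list shift of 0.3 was also larger than every real list median, the farthest from 0 being -0.26. The alternatives tried were other filters on dim genes, median centring, quantile normalization, cyclic loess, the mean of a gene's probe sets, other fold thresholds, an intensity trend in eBayes, the fit without the other factor, and for lists unmatched random lists, the mean, and all members.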

Results

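The data were 4 whole-transcript array profiles: A549 and H441 lung adenocarcinoma cells, each with siNTC and with siTAZ, 1 array per combination. The design asks which genes differ in expression after TAZ is silenced in each line. Median log2 signals were 6.05 and 6.06 on the A549 arrays with siNTC and siTAZ, and 6.17 and 6.25 on the H441 arrays. The 2 arrays of a line correlated at r = 0.994 in A549 and 0.995 in H441 across all probe sets, against 0.916 between the siNTC arrays of the 2 lines. Values within a line are single arrays without replicates, and differences are siTAZ minus siNTC on the log2 scale unless stated otherwise.

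WWTR1, the gene of TAZ, was the most strongly lowered gene in both lines. Its signal was 10.04 with siNTC and 7.64 with siTAZ in A549, a 5.27-fold lower value that left 19.0% of the control signal. In H441 it was 9.61 and 7.47, 4.40-fold lower, with 22.7% left. Over both lines WWTR1 fell by 2.27 ± 0.12 (limma SE, 2 lines, limma adjusted p = 1.5e-11). Every SE given here is the moderated one of the limma fit. It draws mostly on the prior over all genes, so it does not measure the spread between the 2 lines for that gene. YAP1, the paralog of TAZ, had differences of 0.21 in A549 and 0.10 in H441 and did not pass the test (limma adjusted p = 0.65). TEAD1, which encodes a DNA-binding partner of both, had differences of -0.24 and -0.31 (adjusted p = 0.28).

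**Figure D1:**
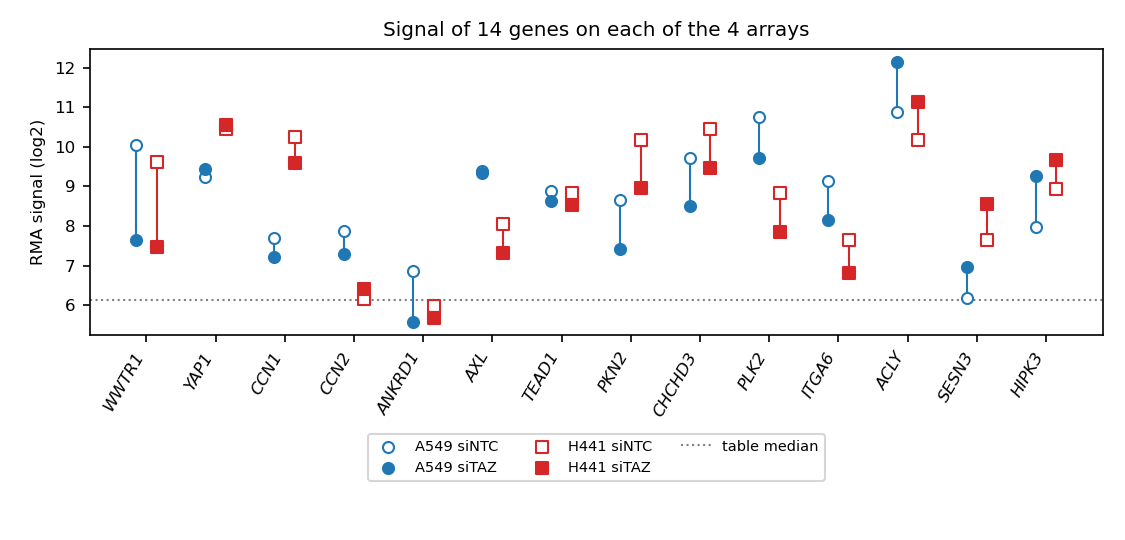
RMA signal (log2, vertical axis) of 14 genes on each of the 4 arrays; open symbols are siNTC, filled symbols siTAZ, circles A549 and squares H441, and each point is 1 array. WWTR1 dropped from 10.04 to 7.64 in A549 and from 9.61 to 7.47 in H441, PKN2, CHCHD3, PLK2 and ITGA6 were lower and ACLY, SESN3 and HIPK3 higher after siTAZ in both lines.

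Among 22 established YAP/TAZ target genes, CCN1 and ANKRD1 fell over both lines and the other 20 did not pass the test over all genes. Of the 22, 9 had an unadjusted limma p under 0.05, against 1688 of all 12740 tested genes. CCN1, which encodes a matricellular protein, was 1.39-fold lower in A549 and 1.56-fold lower in H441 (mean -0.56 ± 0.12 SE, limma adjusted p = 0.0087). ANKRD1, an ankyrin repeat gene, was 2.44-fold lower in A549 and 1.24-fold lower in H441 (-0.80 ± 0.15 SE, adjusted p = 0.0044), with its H441 signal below the table median on both arrays. Adjusted over the list alone, 6 members passed, all lower: MYOF, CCN1, ANKRD1, AXL, FJX1 and NUAK2. CCN2 had differences of -0.58 in A549 and 0.24 in H441 (adjusted p = 0.69), the latter 0.15 after median centring or quantile normalization. AXL, a receptor tyrosine kinase gene, had -0.06 and -0.72 (adjusted p = 0.15), and NT5E had 0.97 and -0.18 (adjusted p = 0.27). In H441, 16 of 21 members were lower, and the list's median of -0.15 (-0.24 after median centring) lay at percentile 0.225 of the matched random lists. In A549, 12 of 20 were lower and the median of -0.04 lay at percentile 18.45, while the mean of -0.14 lay at percentile 0.24. Of the Hippo pathway and TEAD components, 0 of 20 tested passed the limma test over all genes, with 4 at an unadjusted p under 0.05. LATS1, an upstream kinase gene, passed when adjusted over the list alone, with differences of 0.45 and 0.39. STK3 had 0.53 and -0.25, WWC1 -0.47 and -0.12, and VGLL4 0.38 and 0.19. This list's medians were 0.04 in A549 (percentile 74.2) and -0.12 in H441 (percentile 2.55, or 1.32 of unmatched lists and 2.37 with the mean of probe sets).

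In A549, 48 genes differed at least 2-fold, 36 higher and 12 lower after siTAZ. The genes most raised in signal were UHMK1 (3.58-fold, a kinase gene), CACNA2D1 (3.30-fold, a calcium channel subunit), NEK7 (3.21-fold, a mitotic kinase gene), SMIM14 (3.15-fold), PLSCR4 (3.12-fold), TMEM64 (2.92-fold), CENPK (2.88-fold, a kinetochore gene), TP53INP1 (2.73-fold, a p53-induced gene), PLEKHA1 (2.69-fold) and TMEM65 (2.65-fold). After WWTR1, the most lowered were NECAP1 (2.90-fold, an endocytosis gene), ANKRD1, SERPINE2 (2.34-fold, a protease inhibitor), PKN2 (2.33-fold, a kinase gene), CHCHD3 (2.32-fold, a mitochondrial inner membrane protein), YWHAH (2.30-fold, a 14-3-3 protein), HMOX1 (2.24-fold, heme oxygenase), CSRP1 (2.18-fold) and BNIP2 (2.13-fold). TMEM64 and SERPINE2 did not pass the limma test over both lines (adjusted p = 0.064 and 0.14). At 1.5-fold, 201 genes were higher and 122 lower.

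In H441, 5 genes differed at least 2-fold, 1 higher and 4 lower. CHI3L1, a secreted chitinase-like protein, was 2.16-fold higher. Besides WWTR1, DKK1, a secreted Wnt antagonist, was 3.59-fold lower, PKN2 2.34-fold lower, and VGLL1, a TEAD cofactor gene, 2.02-fold lower. At 1.5-fold, 57 genes were higher and 116 lower. With median centring of each array, which moved the median H441 difference from 0.0048 to -0.08 and lowers every H441 difference alike, the 2-fold count in H441 was 10, of which 9 were lower.

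Over both lines, 315 genes passed the limma test, 151 higher and 164 lower after siTAZ, and 1688 had an unadjusted p under 0.05. After median centring the split was 123 higher and 277 lower. All 315 had the same sign in both lines. ACLY, the ATP-citrate lyase that supplies cytosolic acetyl-CoA, rose 2.40-fold in A549 and 1.93-fold in H441 (1.11 ± 0.12 SE, adjusted p = 1.2e-05). TMEM65 (1.10 ± 0.13 SE, adjusted p = 3.6e-05), ZC3HAV1L (1.06 ± 0.13 SE), HIPK3 (1.27 in A549 and 0.74 in H441, a kinase gene), TK2 (0.92 ± 0.12 SE, mitochondrial thymidine kinase), SESN3 (0.84 ± 0.12 SE, a sestrin), C5orf24 (0.84 ± 0.12 SE), CCNG2 (0.84 ± 0.12 SE, cyclin G2), CA11 (0.75 ± 0.12 SE) and UHMK1 (1.27 ± 0.17 SE) rose as well. Besides WWTR1, PKN2 fell by 1.23 ± 0.12 SE (adjusted p = 1.7e-06), with differences of -1.22 and -1.23 in A549 and H441. CHCHD3 fell by 1.11, PLK2, a polo-like kinase gene, by 1.02, YWHAH by 1.02, ITGA6, integrin alpha 6, by 0.91, GK5 by 0.87, DCTN5, a dynactin subunit, by 0.83, LYN, a Src-family kinase gene, by 0.81 and ERLIN1 by 0.80, each ± 0.12 SE. Some calls came mainly from 1 line: CACNA2D1 (adjusted p = 0.022) had differences of 1.72 in A549 and 0.04 in H441, where its signal was below the table median. TP53INP1 (adjusted p = 0.0068) had 1.45 and 0.23, with its H441 signal below the table median as well. DKK1 (adjusted p = 0.0002) had -0.60 in A549 and -1.84 in H441.

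The count of calls depended on the processing. After cyclic loess of the arrays 20 calls were left, all among the 315: WWTR1, PKN2, CHCHD3, PLK2, YWHAH, ITGA6, GK5, LYN, DCTN5, ERLIN1, HSP90AA6P, ACLY, TMEM65, ZC3HAV1L, HIPK3, TK2, SESN3, C5orf24, CCNG2 and CA11, so that every other gene written here as risen or fallen after siTAZ lost its call there. Their limma adjusted p was then 0.00044 for WWTR1, 0.014 for PKN2, 0.023 for ACLY and 0.027 for CHCHD3 and PLK2. The rest, apart from HSP90AA6P, whose value is not given here, had 0.046, just under the threshold. ALDOC lost its call under each alternative filter, scaling and use of probe sets (adjusted p of 0.053 to 0.14). Without the filter on dim genes ANKRD1, CCN1, ANLN, ANXA3, BCL2L1, CACNA2D1, ENO2, HMOX1, NEK7, RFC5, RRM2, SMIM14, THY1, TP53INP1, TPM1 and VGLL1 lost theirs. After quantile normalization all of these but ANKRD1, CCN1, NEK7 and SMIM14 lost theirs. ENO2 also lost it after median centring, and ANLN, CACNA2D1 and HMOX1 under the stricter filter. ANKRD1, THY1 and VGLL1 were too dim to be tested under that filter. Without the cell line in the fit limma called 0 genes, with 11 at an unadjusted p under 0.05, since the difference between the lines then entered the spread.

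The 2 lines' differences were correlated across the 12740 genes (Pearson r = 0.322, Spearman correlation 0.251; r = 0.317 without WWTR1), where genes are not independent replicates. The lines share no array, so no control is common to both. At least 1.5-fold, 23 genes were higher in both lines and 25 lower in both, against 0.908 and 1.14 for independent lists of those sizes, and 0 genes were changed in opposite directions, against 1.85 and 0.559. After median centring, 13 were higher in both and 37 lower in both. Of 203 such genes raised 1.5-fold in A549, 176 were also higher in H441, with a median difference there of 0.23. Of 125 lowered in A549, 96 were also lower in H441, with a median of -0.29.

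**Figure D2:**
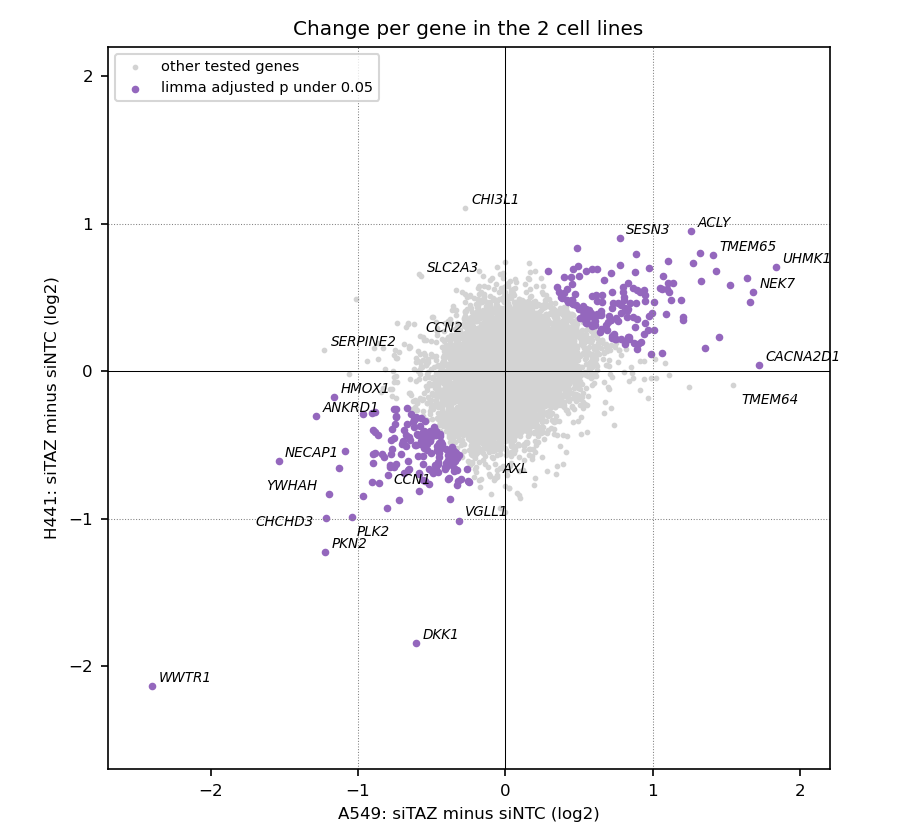
Difference siTAZ minus siNTC (log2) in A549 (horizontal axis) and H441 (vertical axis), 1 point per tested gene; purple points are the 315 genes with a limma adjusted p under 0.05 over both lines and dotted lines mark 2-fold. The called genes lie to the lower left and upper right of the centre, with WWTR1 farthest from the centre, and no gene passes 1.5-fold in opposite directions.

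By list medians, cholesterol synthesis genes were the only one of the 21 lists that stood apart in both lines in the same direction, with 15 of 18 members higher in each. The list's median was 0.22 in A549 (percentile 99.99) and 0.13 in H441 (percentile 99.95). The H441 median was 0.05 after median centring, with 10 of 18 higher, and 0.20 after cyclic loess. By list means, the YAP/TAZ target genes also stood apart in both lines, lower in each (-0.14 at percentile 0.24 in A549 and -0.18 at percentile 0.03 in H441). INSIG1, the sterol-regulated SREBP anchor, had differences of 0.34 and 0.46, LSS, lanosterol synthase, 0.39 and 0.22, and SC5D 0.27 and 0.19, while HMGCS1, the HMG-CoA synthase, had -0.40 and 0.12. Over all genes 0 members passed the limma test and 2 had an unadjusted p under 0.05 (INSIG1 adjusted p = 0.074), and INSIG1 alone passed when adjusted over the list alone.

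Lung epithelial differentiation genes stood apart in H441, where 16 of 17 members were higher after siTAZ (median 0.25, percentile 99.98). SFTPB, surfactant protein B, was 1.60-fold higher, SLC34A2, the alveolar type II phosphate transporter, 1.51-fold and FOXA2 1.29-fold. The exception was CAV1, caveolin 1, a marker of alveolar type I cells, which fell over both lines (-0.59 ± 0.12 SE, limma adjusted p = 0.0049) and was the list's only call. Adjusted over the list alone, SFTPB passed as well. In A549 the median was 0.01 (percentile 54.0).

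G2/M and mitosis genes were lower in H441 for 36 of 37 members, with a median of -0.26, below all 10000 matched random lists. ANLN, anillin, was 1.68-fold lower, NUSAP1 1.51-fold and CCNA2, cyclin A2, 1.40-fold, and CDK1 had a difference of -0.59. In A549 the median was -0.05 (percentile 5.94). ANLN, with -0.25 in A549 and -0.75 in H441, was the only member to pass the limma test over both lines (adjusted p = 0.033), over all genes and adjusted over the list alone. An unadjusted p under 0.05 was reached by 10 of the 37 tested members. BIRC5, survivin, had 0.09 and -0.11, and its probe sets disagreed in sign in A549. G1/S and DNA replication genes had medians of -0.06 in both lines, at percentile 2.43 in A549 (24 of 33 lower) and 26.3 in H441 (24 of 34 lower). The A549 list was inside the random range against unmatched lists (percentile 3.625), by its mean (3.04) and with all members kept (2.76). RRM2, a ribonucleotide reductase subunit, fell (-0.53 ± 0.12 SE, adjusted p = 0.013) and RFC5, a clamp loader subunit, rose (0.52 ± 0.12 SE, adjusted p = 0.021), and the other 32 tested members did not pass, with the same 2 when adjusted over the list alone. POLA1 had -0.38 and -0.34 and POLE2 -0.28 and -0.39.

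**Figure D3:**
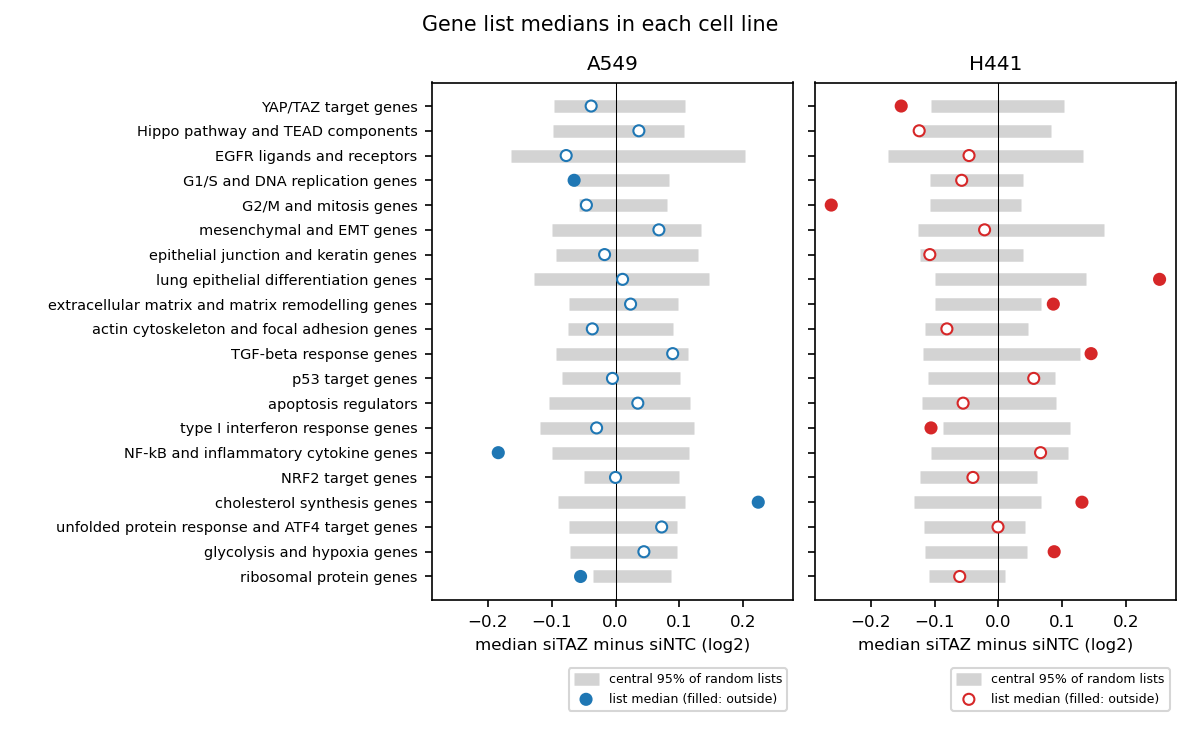
Median difference siTAZ minus siNTC (log2, horizontal axis) of 20 gene lists in A549 (left) and H441 (right); grey bars span the range of 10000 matched random lists outside which a list was said to stand apart, and filled points lie outside them. Cholesterol synthesis genes lie above the bars in both lines, at 0.22 and 0.13, and mitosis genes lie farthest below in H441, at -0.26.

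NF-kB and inflammatory cytokine genes were lower in A549 for 12 of 16 members (median -0.18, percentile 0.04, or -0.08 and 1.33 with all 24 members kept), and had a median of 0.07 in H441 (percentile 87.5), or -0.02 after median centring. Over both lines 0 members passed the limma test and 7 had an unadjusted p under 0.05. The chemokine gene CXCL1 had -0.74 and 0.33 and CXCL2 -0.56 and -0.27 (limma adjusted p = 0.071 for CXCL2, which passed when adjusted over the list alone), while ICAM1 had 0.28 and 0.34 and IL11 0.26 and 0.29. Type I interferon response genes were lower in H441 for 17 of 23 members (median -0.11, percentile 1.03, or -0.19 after median centring and -0.16 after cyclic loess), with -0.73 for SAMD9, -0.50 for IFIT2 and -0.39 for IRF9 but 0.58 for MX2, and 0 members passed the limma test, over all genes or adjusted over the list alone, with 3 at an unadjusted p under 0.05. In A549 that median was -0.03 (percentile 28.5), or 0.0027 after cyclic loess and 0 with all members kept. Glycolysis and hypoxia genes were higher in H441 for 22 of 25 members (median 0.09, percentile 99.9), and had a median of 0.04 in A549 (percentile 77.0). Against unmatched lists the H441 median was inside the random range (percentile 95.85). The size in H441 depended on the processing: the median was 0.0036 after median centring, with 13 of 25 higher, and 0.14 after cyclic loess, and the mean was 0.18. In that list ENO2, neuronal enolase (0.46 ± 0.12 SE, adjusted p = 0.033), and ALDOC, aldolase C (0.44 ± 0.12 SE, adjusted p = 0.0499), rose over both lines, VEGFA had 0.24 and 0.63 and passed when adjusted over the list alone, and the glucose transporter gene SLC2A3 had -0.58 and 0.64.

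TGF-beta response genes had medians of 0.09 in A549 (percentile 94.3) and 0.15 in H441 (percentile 98.8), and TGFBR1, the type I receptor gene, rose (0.69 ± 0.12 SE, limma adjusted p = 0.0014). TGFBR2 and BAMBI, a pseudoreceptor gene, passed only when adjusted over the list alone, with 0.47 and 0.25 for TGFBR2 and 1.11 and -0.02 for BAMBI. SKIL had 0.22 and -0.48. The mean of the list in A549, 0.17, lay at percentile 99.36. Extracellular matrix and remodelling genes had medians of 0.02 (percentile 61.8, and -0.0016 after quantile normalization) and 0.09 (percentile 99.2). PLAU, urokinase, fell (-0.67 ± 0.12 SE, adjusted p = 0.0019) and was the list's only call, against 3 higher and 2 lower when adjusted over the list alone. COL4A1 had -0.69 and 0.19, ITGAV 0.62 and 0.24. Both of these H441 lists were inside the random range after cyclic loess, at percentiles 93.85 and 91.03, and their H441 medians were 0.06 and -0.01 after median centring. By their means, neither stood apart in H441 (percentiles 95.26 and 97.45). Ribosomal protein genes had a median of -0.05 in A549 (percentile 0.655, 24 of 31 lower), inside the range of unmatched lists (percentile 6.91). In H441 their median was -0.06 (percentile 32.7), or 0.02 after cyclic loess. The limma test made 0 calls among them, over all genes or over the list alone, with 2 at an unadjusted p under 0.05. Their named members RPL34, RPL10A, RPL13 and RPS13 had A549 differences between -0.31 and -0.10.

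By matched medians, the other 9 lists stood apart in neither line. For EGFR ligands and receptors the medians were -0.08 in A549 and -0.05 in H441, or 0 and 0.0079 with all 11 members kept, with 0 limma calls over all genes or over the list alone and 2 genes at an unadjusted p under 0.05. EREG, epiregulin, had -0.74 and -0.03, NRG1 -0.50 and 0.21, EGFR -0.27 and -0.32. Mesenchymal genes had 0.07 and -0.02, and THY1 rose (0.53 ± 0.12 SE, limma adjusted p = 0.014), with its H441 signal below the table median. Epithelial junction and keratin genes had -0.02 and -0.11, the latter apart from unmatched lists (percentile 1.61) and after cyclic loess (1.86), with 0 limma calls over all genes or adjusted over the list alone and 4 genes at an unadjusted p under 0.05. CLDN1 had -0.74 and -0.07 and KRT7 -0.25 and -0.42. Actin cytoskeleton and focal adhesion genes had -0.04 and -0.08 (0.01 in H441 after cyclic loess), where TPM1, tropomyosin 1 (-0.52 ± 0.13 SE, adjusted p = 0.022), and ANXA3 (-0.44 ± 0.12 SE, adjusted p = 0.046) fell, and ANXA1 also passed when adjusted over the list alone. In the p53 target list (-0.0048 and 0.06, and -0.03 in H441 after median centring), PLK2 fell and TP53INP1 rose (0.84 ± 0.17 SE, adjusted p = 0.0068). Among apoptosis regulators (0.03 and -0.06), BCL2L1, which encodes the survival protein BCL-XL, fell (-0.65 ± 0.13 SE, adjusted p = 0.0046). Among NRF2 target genes (-2.5e-05 and -0.04, or 0.0084 in A549 after quantile normalization and 0.03 in H441 after cyclic loess, with a mean in A549 of -0.08 that stood apart at percentile 0.32), HMOX1 fell (-0.67 ± 0.16 SE, adjusted p = 0.018), with -1.16 in A549 and -0.17 in H441. In the mesenchymal, p53, apoptosis and NRF2 lists the same calls were made when adjusted over the list alone. Unfolded protein response genes had 0.07 and -0.00055 (0.04 in H441 after cyclic loess and 0.01 with all members kept) and 0 limma calls over all genes, with 5 at an unadjusted p under 0.05 and -0.84 and -0.14 for VLDLR, the only one to pass when adjusted over the list alone. Markers of leukocytes, endothelium and erythroid cells, of which 3 were above the table median in A549 and 4 in H441, had medians of 0.02 and 0.01 (-0.07 in H441 after median centring, and -0.01 in A549 with all members kept), with 0 limma calls, over all genes or adjusted over the list alone, and 1 gene at an unadjusted p under 0.05. Of these CD14, a monocyte marker, had 0.72 in A549.

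The 2 lines differed far more from each other than by siRNA. With 2 arrays per line, 3021 genes differed at least 2-fold (limma adjusted p under 0.05), 923 higher in A549 and 2098 higher in H441. The 2 arrays of a line are its siNTC and siTAZ cultures and not repeats, so these p-values rest on the same 1 residual degree of freedom and prior. Culture or array differences between the lines cannot be told apart from the line itself. The highest in A549 over H441 were ALDH1A1, an aldehyde dehydrogenase (8.63 ± 0.12 SE on the log2 scale), AKR1C2 (7.09), CNTN1 (6.96), AKR1B10 (6.90), GPX2 (6.62), CA12, SPP1, osteopontin (6.18), and KYNU (6.17). In H441 the highest were MAL2 (-7.75 as A549 minus H441), TXNIP (-7.48), CDH3, P-cadherin (-6.53), ARHGDIB (-6.49), TMEM45B (-6.47), UCA1 (-6.40), STEAP4 (-6.35) and AZGP1 (-6.31). NRF2 target genes were higher in A549 for 13 of 22 members and in H441 for 0, and epithelial junction and keratin genes were higher in H441 for 17 of 22 and in A549 for 0. Lung differentiation genes were higher in H441 for 8 of 19, among them SLC34A2 (-5.22) and SFTPB (-2.01), and in A549 for 1. The median of all genes lay 0.31 lower in A549, and after quantile normalization, which removed that shift, the split was 1322 higher in A549 and 1216 higher in H441, with 16 of 22 NRF2 genes and 15 of 22 epithelial genes on their side.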

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

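The tests of array noise, of scaling for the number of calls and of scaling for the number of 2-fold changes were specified before their results were seen; the other tests in this part were chosen after. The size limits behind the first 2 paragraphs below were also set after the values were seen, as was the choice to count lowered probe sets. The scaling test was first set for all genes changed alike, and the number of limma calls met what it had named as the mark of scaling, with 20 of 315 kept. The test of the genes at least 1.5-fold changed alike was split from it only after that result. The rules by which that number of calls and the G1/S test are read were changed after their values were seen, and both are left open.

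Several results had opposite signs in the 2 lines by more than the spread across genes in each, and the difference between lines could not be tested with 1 array per group. CCN2 had a difference of -0.58 in A549 and 0.24 in H441, but its H441 value was 0.15 after median centring or quantile normalization and 0.19 after cyclic loess, inside the H441 spread of 0.22. For CHI3L1 the values were -0.27 and 1.11, but its A549 signal was below the table median on both arrays, so its sign there is not relied on. STK3 had 0.53 and -0.25, ARHGAP29 0.28 and -0.42, and DNAJC3 0.56 and -0.23, the last -0.19 after quantile normalization and -0.18 after cyclic loess, inside that spread as well. CXCL1 had -0.74 and 0.33, and SLC2A3 -0.58 and 0.64. The NF-kB and cytokine list was flagged for the signs of its medians alone, -0.18 in A549 and 0.07 in H441, where it lay inside the random range (percentile 87.5) and was -0.02 after median centring.

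Outside the gene table, 7 of the 2965 probe sets without a single gene symbol and above the table median were at least 1.5-fold lower after siTAZ in both lines, 0 were higher in both and 1 moved in opposite directions. Probe set 8058614 had -0.92 in A549 and -1.03 in H441, and probe set 8127841 had -0.85 and -0.90. Of the 7, 1 was assigned to several genes, all of the NPIPB family, and the others have no gene name here.

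The first pattern is the set of genes that changed alike in both lines. Array noise with no shared response is argued against, because exchanging the siRNA labels of the A549 arrays gave 0 limma calls against 315, with 147 genes at an unadjusted p under 0.05 against 1688. That test is partly built in, since genes that moved alike widen the spread of the exchanged fit; 48 genes at least 1.5-fold changed alike and 0 in opposite directions do not have that limit. Cyclic loess kept 43 of the 48 genes at least 1.5-fold changed alike, which argues against scaling as the source of most of them. Their split by direction did depend on scaling: 23 higher and 25 lower became 13 and 37 after median centring. Scaling stays open for the number of calls, of which 20 were kept after cyclic loess. There the prior degrees of freedom went from 22.3 to 7.22 while folds barely moved (UHMK1 from 1.27 to 1.31, CAV1 from -0.59 to -0.56). Without a filter on dim genes 92 calls were left, with the scaling unchanged. Known YAP/TAZ targets made up 2 of the 164 genes called lower (0.283 by chance), and a list of 22 genes cannot show how many of the rest are targets; an effect of the siRNA sequences apart from TAZ stays open and cannot be told apart from loss of TAZ, since the labels hold 1 siRNA name for TAZ, which leaves open whether it was a pool, and no array of untransfected cells was used here; lowered genes such as PKN2 and CHCHD3 may be of either kind.

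The second pattern is the lower mitosis genes in H441. A brightness-dependent difference between the 2 arrays is argued against, because the list's median of -0.26 lay below all 10000 random lists matched on mean expression. After cyclic loess the median was -0.24, still below all matched random lists. That adds little, since the matching had already allowed for brightness. Fewer cells in the whole cell cycle stays open, because G1/S genes lay at percentile 26.3 in H441 (median -0.06) with 24 of 34 members lower, and at 6.86 of unmatched lists, 10.35 by the mean and 13.91 after cyclic loess (median -0.03), which decides neither way. A change in the mitotic part of the cycle, or in how the 2 dishes were grown, stays open too and was not tested.

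The third pattern is the larger number of 2-fold changes in A549 than in H441. Scaling is argued against, with 53 genes in A549 and 6 in H441 after quantile normalization. A smaller knockdown in H441 stays open: the H441 to A549 ratio was 0.892 for the WWTR1 differences and 0.794 for the median absolute differences of the other called genes, and single arrays give no spread for either. Among the called genes the gap lay in those raised, whose medians were 0.75 in A549 and 0.45 in H441, against -0.55 and -0.54 for the lowered genes. Calls favour genes that changed alike in both lines, so these medians and the ratio of 0.794 do not speak for all changed genes. Biological differences between the lines were not tested.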

How the results depend on the processing

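All alternatives here were set before the data were examined. Among 120 named genes, 240 of 240 single-line differences moved by less than the spread across genes under quantile normalization, and 240 of 240 under cyclic loess. Median centring shifts all genes of a line alike by less than that spread. The mean of probe sets cannot move a gene with 1 probe set, and RPL34 in H441 moved by more than the spread under it. The 2 arrays of a line already had similar distributions, with medians of 6.05 and 6.06 in A549 and 6.17 and 6.25 in H441. Rescaling could therefore hardly move a difference by that spread, so these counts do not test whether the single-line values hold. The 315 limma calls over both lines became 594 with an intensity trend, 92 without a filter on dim genes, 142 after quantile normalization (75 higher, 67 lower), 20 after cyclic loess and 0 without the cell line in the fit (11 at an unadjusted p under 0.05), with 310, 92, 142 and 20 of the first 4 shared with the 315; they were 253, 300 and 400 under the stricter filter, the mean of probe sets and median centring. The prior degrees of freedom went from 22.3 to 211, 9.16, 10.4, 7.22 and 1.74 in the first 5, and the cause was not tested. Median centring moved the split of calls to 123 higher and 277 lower, and that of the genes changed alike to 13 higher and 37 lower, by a shift of the H441 median of -0.08. At 1.5-fold, 323 genes differed in A549 and 173 in H441, and median centring gave 10 2-fold genes in H441; the count in A549 stayed between 47 and 53 otherwise. At 2-fold in both lines, 2 genes changed alike, WWTR1 and PKN2, against 48 at 1.5-fold, and the other alternatives gave 45 to 50. A549 against H441 gave 2457 to 3074 genes, with the share higher in A549 going from 30.6% to 41.0% (median centring), 52.1% (quantile) and 52.7% (cyclic loess). Of the lists standing apart, A549 had 4 and H441 had 8; unmatched random lists left 2 in A549, and the rest gave 3 to 6 in A549 and 6 to 9 in H441. The cholesterol (both lines), YAP/TAZ target, mitosis, lung differentiation and interferon lists (H441) and the NF-kB list (A549) stood apart under all 5 list alternatives; the G1/S list in A549 and the matrix list in H441 did so under 2, TGF-beta in H441 under 3, and glycolysis in H441 and ribosomal genes in A549 under 4. The mean of a list had the other sign than its median for the lung differentiation (-0.06), matrix (-0.02), apoptosis (-0.02) and unfolded protein response (-0.04) lists in A549 and the p53 list in H441 (-0.0014), each inside the random range. The main fit compares the siRNAs within each line, with the cell line as the only block, and leaving out either line leaves no residual degree of freedom, so the per-line values stand for it. Signal limits dim genes, whose folds RMA compresses, and single arrays limit the rest.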

Other observations

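The family scan and the choice of microRNA lists were made after seeing the main results; the microRNA tests were specified before their medians were computed.

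Genes were grouped by the letters of their symbols before the first digit, and 70 such families had at least 15 measured members. Of 140 family and line combinations, 29 stood apart from 2000 matched random lists, against 7 by chance. That 7 holds only if the members of a family vary independently, which was not tested. The excess is therefore no evidence of a response to siTAZ. Solute carrier genes (SLC) were higher in both lines, 135 of 216 in A549 (median 0.06) and 158 of 223 in H441 (median 0.12). Translation initiation factor genes (EIF) had medians of -0.07 in A549 and -0.13 in H441, and large ribosomal subunit genes (RPL) -0.09 and -0.10, with both families apart in both lines. The RPS family, which holds small ribosomal subunit genes, was apart in neither (-0.04 in each, percentiles 4.175 and 38.05). Grouping by letters also puts any RPS6K kinase gene there, so RPL against RPS is not a clean contrast of large and small subunits. Except for TMEM, RPS and SNORD in H441, the family medians given here kept their sign after median centring, quantile normalization and cyclic loess. In A549, small nucleolar RNAs were lower, with 7 of 40 SNORD genes (median -0.18) and 5 of 22 SNORA genes (median -0.14) above 0, whereas in H441 25 of 47 (0.05) and 18 of 26 (0.08) were above 0, inside the random range. Single members did fall in both lines. Limma over both lines called SNORD44 (-0.69 in A549 and -0.47 in H441), SNORD49A (-0.39 and -0.60), SNORD75 (-0.51 and -0.41) and SNORD79 (-0.38 and -0.55) lower. Also in A549, SEC family genes of the secretory pathway were higher (20 of 23, median 0.16). In H441, the largest increase was in keratin-associated protein genes (KRTAP), which are known from hair, with 25 of 29 higher (median 0.22), and 32 of 41 LINC non-coding RNA genes were higher (0.15), so a shift of the arrays is not set aside for the families higher in H441. Collagen genes were higher for 21 of 23 members (median 0.18) and TMEM genes for 110 of 166 (0.08, or -0.0045 after median centring), whereas 144 of 376 zinc finger genes (ZNF, median -0.05) and 8 of 33 centrosomal genes (CEP, median -0.15) were above 0. The sizes in H441 depended on scaling: SLC had 0.04, collagen genes 0.09, KRTAP 0.14, LINC 0.06, ZNF -0.15 and CEP -0.25 after median centring, and EIF and RPL had -0.05 after cyclic loess.

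PLEKHA1 and TP53INP1 were among the genes higher after siTAZ in A549, which raised relief from a microRNA as a candidate explanation. Lists of miR-21 and let-7 targets were written from general knowledge, without genes already named. Many genes were named for having the largest changes, so leaving them out can draw a list's median towards 0. A median inside the random range therefore does not exclude relief of such targets. The miR-21 targets had a median of 0.0041 in A549, at percentile 48.9 of the matched random lists (12 of 22 higher), and let-7 targets a median of 0.0064 at percentile 48.8 (12 of 23 higher), inside the random range for both. In H441 the percentiles were 37.0 and 80.5.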
